A study of Caenorhabditis elegans with 4 samples.

How the data were processed

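BLMP-1 tagged with GFP was immunoprecipitated from embryos of Caenorhabditis elegans strain OP109, and the bound DNA was sequenced (ChIP-seq). Per the labels, worms were grown at 20 °C and fixed with 2% formaldehyde, sheared chromatin was collected with anti-GFP antibodies, and 10% of each extract was set aside as input. The series holds 2 ChIP samples and 2 input samples, which were grouped and numbered by their titles.

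Analysis began from 3 deposited peak lists, 1 for each ChIP replicate and 1 for the whole series. Per the file headers and source column, peaks came from PeakSeq with coordinates on WormBase WS220. The PeakSeq version, aligner, read filters, calling threshold and use of the inputs are not given in the sources used here, nor is it given whether the list of the whole series was called on pooled reads. Deposited start and end positions were used as they stand, counted from 1. The deposited score of each peak, the authors' own value, ran from 0 to just under 0.001 and was read as a q-value, smaller for stronger peaks. The files do not name it, so this reading was tested on the values. Peaks carry a number, and the score multiplied by that number never fell along the numbering in any list (0 falling steps). Neighbouring products were equal within a relative tolerance of 1e-09 in 83.9% of steps of the series list, 82.5% in replicate 1 and 73.0% in replicate 2. A p-value multiplied by a constant and divided by its rank has this form. Because such a score falls slightly within runs of tied p-values, the product was also used as the strength, an alternative chosen after seeing the data. Score and product ranked the peaks nearly alike (Spearman's rho at least 0.999 in each list).

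Peak numbers also showed that some numbered peaks were not among those analysed here. The series list reached number 18286 with 17858 peaks, so 428 numbers were missing, the first of them 3755. Replicate 1 lacked 148 numbers, the first of them 3136, and replicate 2 lacked 0.

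Read depth is unknown, since the lists give no counts, coverage or library totals, and no interval that needs depth is given. No list of the input samples was analysed here, so there is no background measured in the same way. Chance placements of peaks were used instead, and they do not remove background that both ChIP libraries share. Precision is limited by the number of peaks in each list and by the number of ChIP libraries. The labels do not say whether the 2 replicates came from separate cultures. All p-values therefore describe peaks within these lists and not variation between animals, and nearby peaks are not independent. The replicate lists shared 0 identical intervals and were treated as separate samples.

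Overlap meant at least 1 shared bp and was checked with bedtools 2.31.1. Chance overlap came from 1000 circular shifts of the other list within each chromosome (200 for each strength class), with a one-sided permutation p that cannot fall below 0.001. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Strengths were compared by two-sided permutation tests with 100000 resamples, 10000 for alternatives, and the smallest possible p of the former is 1e-05. Scores of 0 took the smallest score above 0 in their list for logarithms. Peaks per Mb used the last peak end on each chromosome over all 3 lists as its length, 100.2 Mb in total. Chromosomes were compared by two-sided exact binomial tests with Benjamini-Hochberg adjustment over 6 chromosomes in each list. Middle and outer parts of the autosomes were compared by 1000 circular shifts. Spacing was compared with 1000 uniform random placements, or 200 where placed peaks were merged. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with a fixed seed. The overlap test was tested on simulated data: with 40% of 3009 replicate 2 peaks planted in a random list, 43.4% were recovered against 43.8% planted or overlapping by chance, and 3 of 40 simulations without planting gave a p under 0.05.

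Tests, main settings and most alternatives were fixed before the data were examined. Those alternatives were overlap by 50% of the shorter peak, midpoints within 200 bp, the stronger 50% of each list, equally long replicate lists, other chance placements, one-to-one matches, peak width or percentile rank as strength, each replicate list in place of the series list, and neighbour gaps of 500 and 5000 bp. Chosen after seeing the data were the product strength, random placement with merged peaks, leaving out chromosome I, an equally long top list for chromosomes, and leaving out peaks wider than 3000 bp.

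The rule for named genes was to name the genes beside the 10 strongest peaks of the series list and the bound members of fixed gene lists. It provided that, without an annotation of the same build, no gene is named and the 10 strongest peaks are given by position, and that is what was done. The gene table used here follows assembly WBcel235, not WS220, so no peak was assigned to a gene. From that table only the chromosomes of blmp-1 (I) and unc-119 (III) entered the results. Gene positions of WBcel235 were also compared by eye with the widest WS220 regions during exploration. As this mixes builds, no result rests on it and its outcome is not reported, but it was known when the tests of extra DNA copies were chosen. Distance to transcription starts, target gene counts, gene list enrichment, the BLMP-1 motif and peaks at the blmp-1 and unc-119 genes were left out for this reason.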

Results

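BLMP-1 binding was mapped in embryos of Caenorhabditis elegans by ChIP-seq, that is, immunoprecipitation of chromatin followed by sequencing. BLMP-1 is a zinc finger transcription factor related to mammalian Blimp-1. Strain OP109 carries a transgene that expresses BLMP-1 fused to GFP, in an unc-119 mutant background rescued by an unc-119 copy on the same construct, and GFP served as the handle for precipitation. There were 2 ChIP samples and 2 input samples of total chromatin DNA. Peaks were analysed in 3 lists, 1 for each ChIP replicate and 1 for the whole series. No input list was analysed here, and the read depth of all samples is unknown.

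Called peaks were many and mostly narrow. Whether and how the inputs were used in calling them is not given in the sources used here. No input data were analysed here, so the peaks are not shown to be binding sites. The list of the whole series held 17858 peaks with a median width of 149 bp (quartiles 65 and 236 bp) and covered 3.41% of the genome span. Replicate 1 gave 11261 peaks with a median width of 162 bp, covering 2.22%. Replicate 2 gave 3009 peaks, wider at a median of 300 bp and covering 1.08%, so replicate 1 held 3.74 peaks for each peak of replicate 2. Peaks under 50 bp made up 20.5% of the series list and 16.7% of replicate 1 but 0.665% of replicate 2. Stronger peaks were wider in each list, with Spearman's rho across peaks of 0.638, 0.685 and 0.669 in the series list, replicate 1 and replicate 2. Scores, read here as q-values, fell below 1e-10 for 1418 series peaks, 617 replicate 1 peaks and 239 replicate 2 peaks.

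The lowest scores of the series list belonged to a few regions far wider than a typical peak. A score of 0 was listed for 4 series peaks. These were chromosome II 9897273 to 9903210 (5938 bp), IV 11694533 to 11700856 (6324 bp), V 6350830 to 6354622 (3793 bp) and X 15724964 to 15738314 (13351 bp), all on WS220. The fifth was the widest region of all, chromosome I 10390514 to 10414818 (24305 bp, score 1.34e-291). Then came narrower peaks at IV 10089676 to 10090800, II 8750638 to 8751780, II 8748699 to 8750417, X 15274592 to 15275809 and V 6105149 to 6106291, which were 1125 to 1719 bp wide with scores from 4.8e-223 to 1.04e-158. No input data were analysed here that would separate binding from extra DNA copies in the worms. Input data would not show extra DNA present in 1 ChIP library alone. These regions are therefore not shown to be the strongest binding sites.

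Replicates differed in coverage, or in rank within their own list, at 4 of these 10 positions. The 24305-bp region of chromosome I was a single peak in both, 24251 bp wide in replicate 1 and 24260 bp in replicate 2. The chromosome V region at 6350830 was made of 3 peaks in each replicate, covering 86.4% of it in replicate 1 and 78.7% in replicate 2. In contrast, the regions on II at 9897273 and IV at 11694533 were covered completely in replicate 1 but by 1 short peak each in replicate 2, which took up 4.16% and 2.04% of their length. At X 15724964 replicate 1 covered 99.5% and replicate 2 had no peak. At IV 10089676 both had a peak, which covered 45.0% of the position in replicate 2. The score was 4.89e-237 (rank 5) in replicate 1 and 0.000171 (rank 1631) in replicate 2. The other 4 narrow positions had peaks in both replicates, with best scores of 3.1e-139 to 4.19e-101 in replicate 1 and 8.58e-88 to 4.59e-72 in replicate 2. These are values of single peaks, with no test, and scores of lists of different lengths are not comparable as levels.

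**Figure D1:**
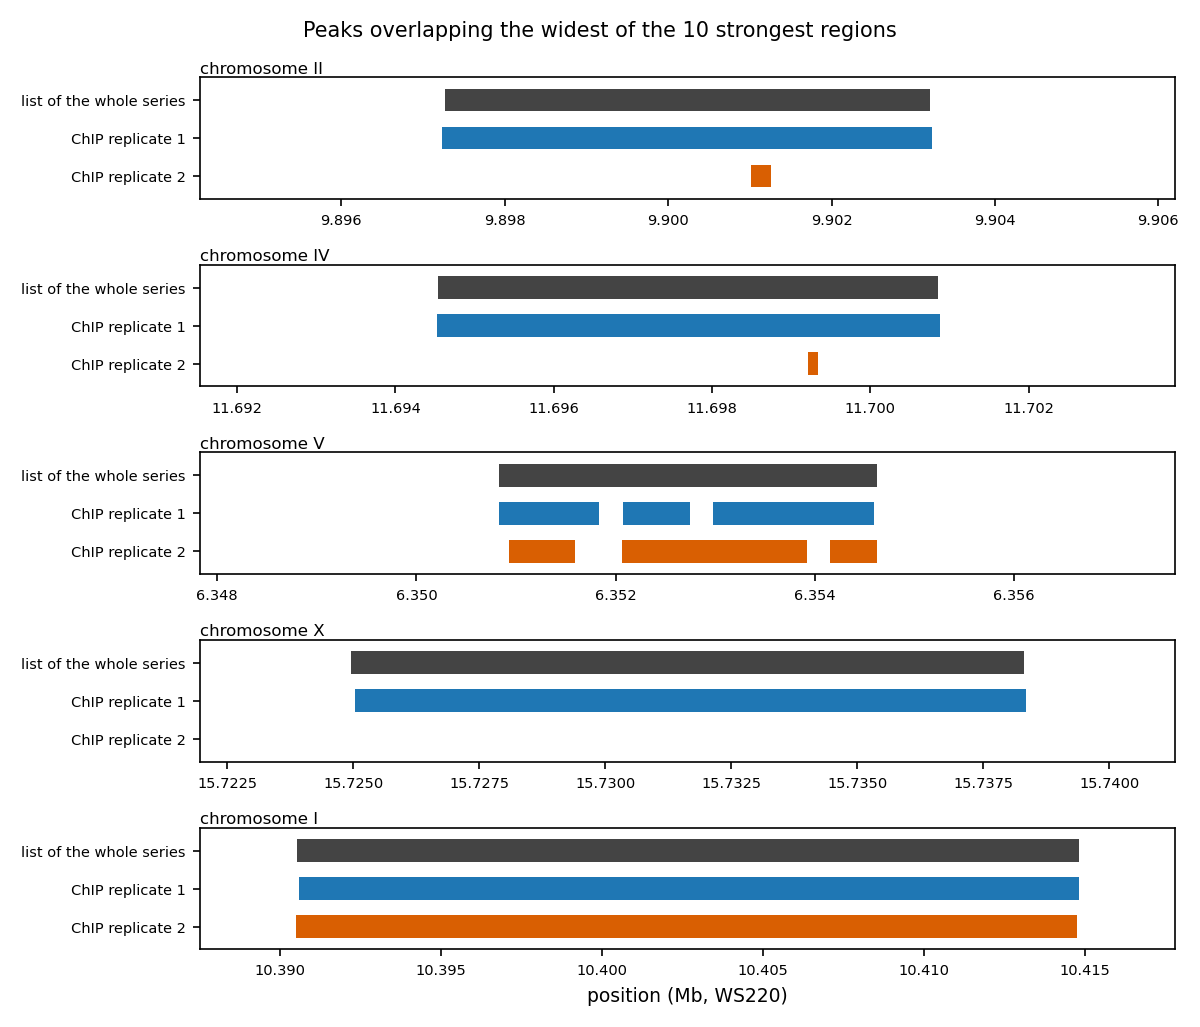
Peaks of the 3 lists at the 5 regions wider than 3000 bp among the 10 strongest of the series list, with position in Mb on WS220 along each horizontal axis and 1 bar for each peak. Chromosome I 10390514 to 10414818 is filled in all 3 lists, while the regions on II and IV are covered to 4.16% and 2.04% in replicate 2 and the region on X holds no replicate 2 peak.

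The first comparison asked how far the peaks of the 2 ChIP replicates overlapped. Chance shifts do not remove background that both libraries share, so overlap above chance does not by itself show BLMP-1 binding. Of the 3009 replicate 2 peaks, 1549 overlapped a replicate 1 peak (51.5%, exact 95% interval 49.7% to 53.3%), which was 8.14-fold the 6.33% found by chance. Of the 11261 replicate 1 peaks, 1552 overlapped a replicate 2 peak (13.8%, interval 13.2% to 14.4%), 8.07-fold the chance level of 1.71%. Both permutation p-values were 0.001, the smallest that 1000 shifts can give. These shares depended on the lengths of the lists: with replicate 1 reduced to its 3009 strongest peaks they were 39.5% and 39.1%, each 17-fold the chance levels of 2.32% and 2.30%. In the stronger 50% of each list, 66.4% of replicate 2 peaks overlapped, 15.5-fold the chance level, and 17.7% of replicate 1 peaks, 15.3-fold.

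Overlap depended strongly on peak strength. Among the strongest 301 peaks of replicate 2, 99.0% were found in replicate 1 (interval 97.1% to 99.8%), against 24% of the weakest 300 (19.3% to 29.2%). Among the strongest 1127 peaks of replicate 1, 72.1% were found in replicate 2 (69.4% to 74.7%), falling to 2.58% of the weakest 1126 (1.73% to 3.68%), where chance gave 1.34%. Shares lay above chance in each of the 10 strength classes of both replicates, with one-sided permutation p-values of at most 0.00995. Shared peaks of replicate 1 had a median score of 3.46e-08, against 0.000217 for the others, and were 351 bp wide at the median against 144 bp. In replicate 2 the median scores were 9.05e-06 and 0.000362, and the widths 348 and 254 bp. The differences in median −log10 score, 3.80 in replicate 1 and 1.60 in replicate 2, each had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give.

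**Figure D2:**
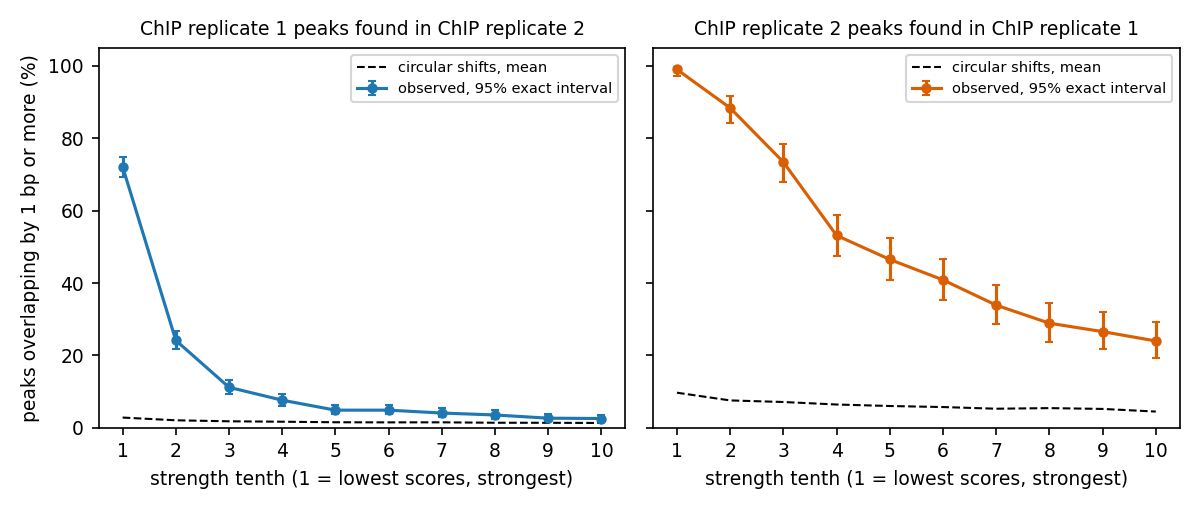
Share of peaks (%) that overlap a peak of the other replicate by 1 bp or more, by strength class from 1 (strongest) to 10, with exact 95% intervals as bars and the mean of circular shifts as a dashed line. Replicate 1 falls from 72.1% to 2.58% and replicate 2 from 99.0% to 24%.

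Scores of peaks found in both replicates went together, with strong exceptions. Across 1549 matched pairs of peaks, scores correlated with Spearman's rho of 0.597 and, on the log10 scale, Pearson's r of 0.686, each with a two-sided permutation p of 1e-05. Peaks are not independent replicates, so these values describe the lists. The regions at II 9897273 and IV 11694533, of score 0 and tied for first in replicate 1, matched replicate 2 peaks of rank 1886 and 1455. IV 10089676, of rank 5 in replicate 1, matched rank 1631. These ranks are within lists of 11261 peaks in replicate 1 and 3009 in replicate 2. Of the 100 strongest replicate 1 peaks, 95 were found in replicate 2 (exact interval 88.7% to 98.4%). The 5 without a replicate 2 peak, named after their values were seen, started at X 15725032, X 7776535, II 11027542, I 7900149 and I 7898886, and 4 of them ranked among the 20 strongest.

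The next comparison set the list of the whole series against the replicates. Only 1623 of its 17858 peaks (9.09%, interval 8.67% to 9.52%) overlapped peaks of both replicates. Another 6432 (36%) overlapped replicate 1 alone and 1059 (5.93%) replicate 2 alone, and 8744 (49.0%, 48.2% to 49.7%) overlapped neither. Peaks found in both replicates were the widest and strongest, at a median of 444 bp and a score of 9.38e-14, and those found in neither were the narrowest and weakest, at 101 bp and 0.000208. Among the stronger 50% of the series list, the share in both replicates rose to 18.1% and the share in neither was 25.2%. In the other direction, 71.8% of replicate 1 peaks and 89.2% of replicate 2 peaks overlapped the series list.

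One strong peak of both replicates was absent from the series list. Chromosome I 15063982 to 15067642 was the fourth strongest peak of replicate 1 (3661 bp, score 4.41e-285), and the strongest peak of replicate 2 spanned 15063999 to 15067642 (3644 bp, 2.04e-312). Both replicate peaks ended at 15067642, which was the last peak end on chromosome I over all lists. The nearest series peak lay 72008 bp before the replicate 1 peak, and the series list held no peak from there to that end. Whether the place of this peak at the end of the listed span bears on its strength was not tested. No peak number below 3755 was missing from the series list. This position was named after its values were seen, and the same caution on extra DNA copies applies to it. The next strongest replicate 1 peak without a series peak, at IV 1664925, ranked 846.

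BLMP-1 peaks were unevenly spread over the chromosomes. Chromosome I held 114 series peaks per Mb, against 192 on II, 207 on III, 196 on IV, 181 on V and 177 on X. Its density was 0.60 of that of the other chromosomes together (interval 0.571 to 0.631, exact binomial adjusted p 1e-101). The same ratio was 0.481 in replicate 1 and 0.402 in replicate 2. Chromosome III was the densest in each list, at 1.19 times the rest in the series list (adjusted p 1.18e-16), 1.41 times in replicate 1 and 1.43 times in replicate 2. Each of the 15 full 1-Mb bins of chromosome I lay below the median bin of the other chromosomes in all 3 lists. In the series list these bins held 51 to 146 peaks against a median of 186.5 elsewhere. Nearby peaks are not independent, so the binomial p-values are too small.

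**Figure D3:**
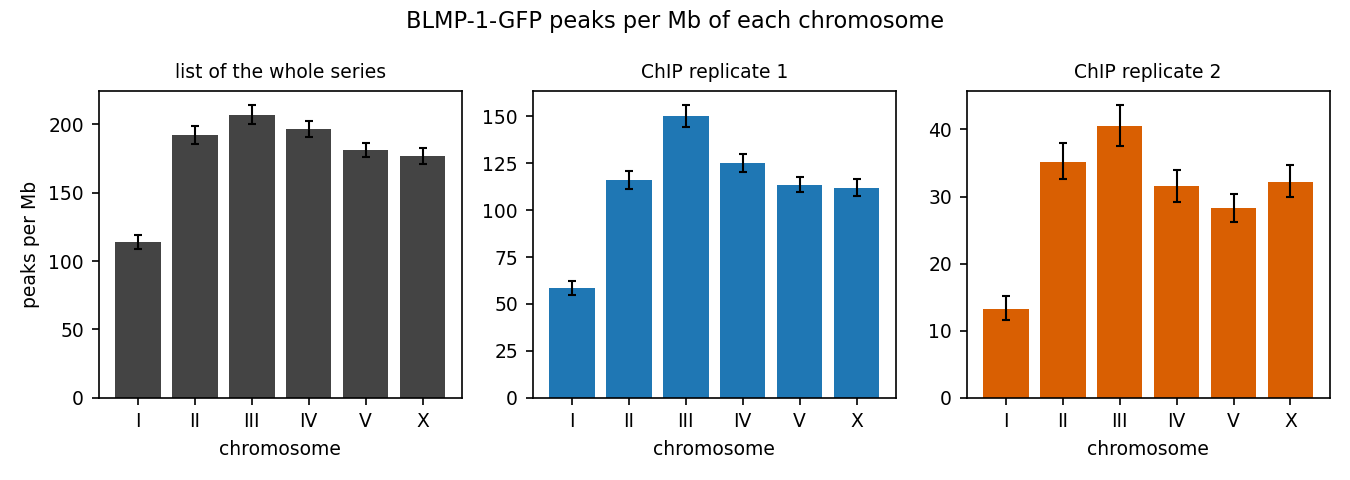
Peaks per Mb of each chromosome in the series list, replicate 1 and replicate 2, on separate vertical scales that start at 0, with exact 95% binomial intervals as error bars. Chromosome I is lowest in each panel, at 114, 58.7 and 13.3 peaks per Mb.

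The X chromosome and the autosomes did not differ in density in the main comparison, with a ratio of 0.990 (interval 0.952 to 1.03, exact binomial p 0.61). Chromosome I lowered the autosomal density: against the other 4 autosomes the X ratio was 0.916 (0.880 to 0.952, p 8.56e-06), a comparison added after seeing the data. In replicate 2 that ratio was 0.971 (0.885 to 1.07, p 0.546). In the 3009 strongest series peaks it was 0.947 (0.860 to 1.04, exact binomial p 0.273). Each interval holds both 1 and the ratio of the series list. The ratio of X to all autosomes was 0.931 (p 0.0111) in the stronger 50% of the series list.

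Over the autosomes together, peaks were slightly denser in the middle parts than towards the ends, with each chromosome divided into 3 equal parts. The ratio was 1.10 in the series list (two-sided permutation p 0.042 with 1000 shifts), 1.11 in replicate 1 (p 0.0829) and 1.35 in replicate 2 (p 0.00699), so replicate 1 alone did not pass the threshold of 0.05. On chromosome II, for example, the series list held 215 peaks per Mb in the middle against 173 on the left and 188 on the right. Chromosome IV did not show this pattern, as its middle, at 192 per Mb, lay between the left part at 190 and the right part at 207.

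**Figure D4:**
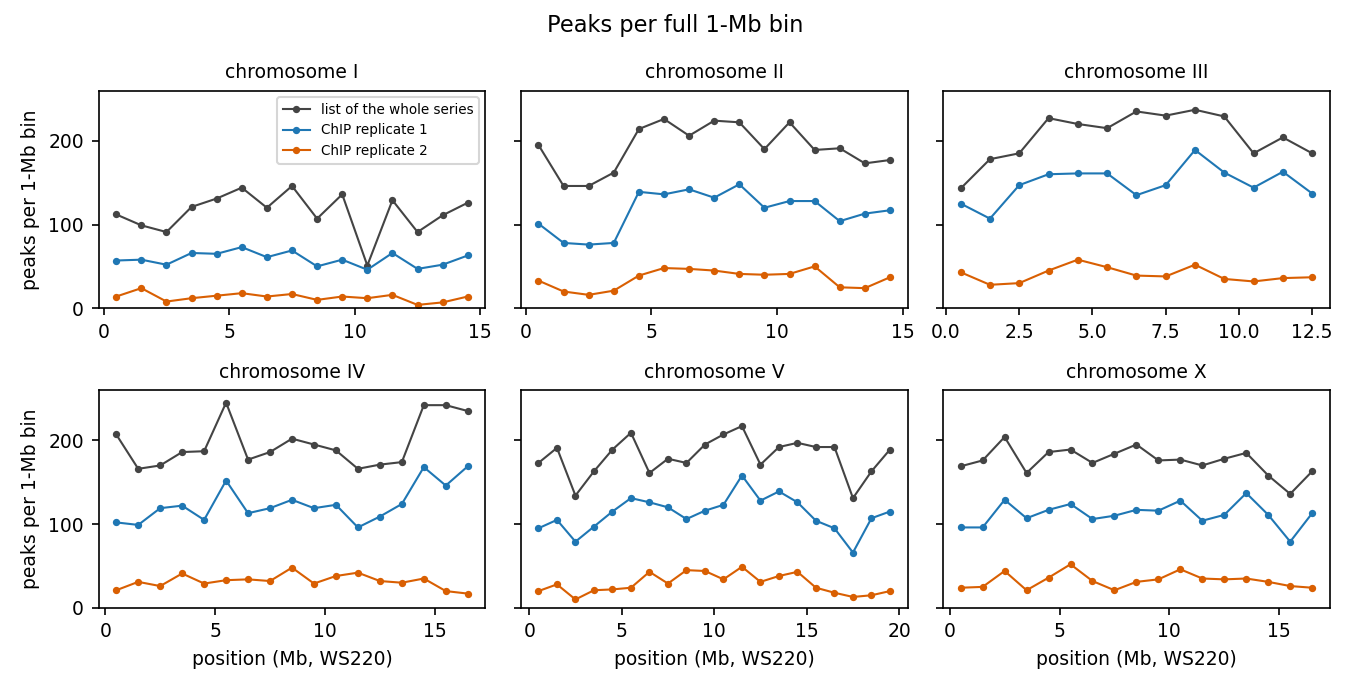
Number of peaks in each full 1-Mb bin along the 6 chromosomes, by midpoint, with position in Mb on WS220 and 1 line for each list. The series list stays at or below 146 on chromosome I, where the bin from 10000001 to 11000000 holds 51, and reaches 245 on chromosome IV.

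Peaks lay close together more often than random placement gives, by a margin that depended on the list and on how peaks were placed. In the series list 36.8% of peaks had a neighbour within 1000 bp, against 35.1% after random placement. The shares were 26.3% against 24.4% in replicate 1 and 15.2% against 8.25% in replicate 2. Each two-sided permutation p was 0.002, the smallest that 1000 placements can give. When placed peaks closer than the smallest gap of the list were merged, a setting added after seeing the data, chance gave 25.2% for the series list, 1.46-fold below the observed share. The densest 100-kb window was chromosome IV 14600001 to 14700000 with 44 series peaks, where the median window held 18, and replicates 1 and 2 had 31 and 4 peaks in it. Within 500 bp the order turned in the series list, at 18.1% against 22.1%, and in replicate 1, at 12.9% against 15%, but not in replicate 2, at 6.68% against 5.29% (one-sided permutation p 0.014). The smallest gaps between peaks were 201, 203 and 204 bp, while randomly placed peaks may lie closer or overlap. The comparison within 500 bp therefore does not set like against like, and no conclusion is drawn from its turn.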

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

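Of 60 alternative values for 14 results, 46 kept their direction and side of the threshold, or for shares of the series list stayed within the 95% interval. Replicate overlap, strength agreement, the strength of shared peaks and the low density of chromosome I kept theirs under each alternative tried. Those that leave out chromosome I or wide peaks, merge placed peaks, use the score multiplied by the peak number or an equally long top list were chosen after seeing the data. With 50% of the shorter peak required, the series list had 35.0% in replicate 1 only and 50.4% in neither. With midpoints within 200 bp, 7.92% were in both. In the stronger 50%, 18.1% were in both, 48.1% in replicate 1 only, 8.57% in replicate 2 only and 25.2% in neither. X against autosomes was 0.931 in the stronger 50%, 0.996 to 1.09 in single replicates and 1.0 in the equally long top list. Without chromosome I it was 0.899 to 0.971 in single replicates and 0.947 in the equally long list, whose fewer peaks widen the interval (0.860 to 1.04). The ratio of middle to outer parts was 1.11 to 1.35 in single replicates. For these the cause was not tested. A neighbour within 500 bp was found for 18.1% of series peaks, below the 22.1% of random placement; placed peaks may overlap, while the list holds no gap under 201 bp. No paired analysis was possible because no input lists were analysed here and no model was fitted over samples. Distance to transcription starts, target genes, gene lists and the motif were not run, for want of a WS220 genome and annotation here. Depth is unknown, so whether it limits replicate 2 was not tested.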

Other observations

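Some stretches without BLMP-1 peaks were longer than random placement gives. The longest in the series list was chromosome V 2342781 to 2565721 (222941 bp), where 1000 random placements gave a longest gap of 69098.5 bp at the median and 127523 bp at most (one-sided permutation p 0.001, the smallest they can give). Replicate 1 lacked peaks over 256738 bp at the same place, from V 2309618 (p 0.001). The gap of replicate 2 there, 392134 bp, was within what random placement of its fewer peaks gives (p 0.675). A second long gap of the series list lay at chromosome I 13865511 to 13997145 (131635 bp, p 0.001). Replicate 1 had no gap there among its 3 longest, and the replicate 2 gap there, 378751 bp, was within chance (p 0.751). The longest gap of replicate 2 was II 1719103 to 2341227 (622125 bp, p 0.048). Dense windows after the first were IV 3800001 to 3900000 with 41 series peaks, 28 of replicate 1 and 21 of replicate 2, and V 1 to 100000 with 40, 22 and 4.

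All tests below were chosen only after the results they bear on, or values closely tied to them, had been seen. The tests of extra DNA copies were also chosen after WBcel235 gene positions had been compared by eye with the widest regions, so they are not independent of that look, which mixed builds and is not reported. Read data of the input samples, where extra DNA copies carried by the worms would appear, were not analysed here. Extra DNA present in a ChIP library alone would not appear there.

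The first pattern was the low peak density of chromosome I, at 0.60 of the rest. Missing peak numbers do not account for it, since placing all 428 of the series list on chromosome I gives a ratio of 0.750 (interval 0.717 to 0.785). A lower density of sites shared by both replicates stays open: chromosome I held 8.87% of replicate 1 and 6.65% of replicate 2 peaks in equally long lists, but Fisher's exact p of 0.00145 sets 1 library against 1 library and decides nothing. A higher effective calling threshold on chromosome I is a candidate explanation that also stays open, as its peaks were wider at matched score in at least 9 of 10 score classes of each list, but those of X were also wider in 9, 8 and 8 classes and those of IV in 8, 7 and 7 (series list, replicates 1 and 2), so this is weak support. Over the 6 chromosomes wider peaks at matched score went with lower density, with Spearman's rho of −0.829 in each list (exact p 0.0583) and −0.7 without chromosome I (p 0.233), so neither passed 0.05.

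The second pattern was that the 3 strongest replicate 1 regions, at II 9897232, IV 11694528 and X 15725032, were covered to 4.12%, 2.03% and 0% by replicate 2. Lower sensitivity of replicate 2 was argued against only weakly. The next 97 replicate 1 peaks were covered to 76.4% at the median and 47.7% at the 10th percentile, although 4 of them were covered to under 5%. Their median width was 915 bp, against 6001 to 13323 bp for the 3 regions, and the share covered may depend on width. Extra copies of DNA segments in the replicate 1 library may account for it. The narrowest of the 3 was 1.64-fold the widest of the next 96 peaks, leaving out the 24305-bp region. That widest peak, 3661 bp at I 15063982, is itself under the same caution on extra DNA copies. The width comparison is weak evidence, since width goes with strength and the 4 other absent peaks were only 712 to 1028 bp wide. Binding present in 1 replicate stays open. No biological explanation was tested, since the labels give no difference between the replicates.

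The third pattern was the 24305-bp region of chromosome I. A merged run of separate sites stays open. The region was 1 peak in all 3 lists, the narrowest 99.8% as wide as the widest, but this was known when the test was chosen. The 3793-bp series region at V 6350830 was 3 peaks in each replicate, but 1 such region for contrast decides nothing. Extra copies of 1 DNA segment in both libraries stay open too. Edges were at most 77 bp apart between replicates, but this too was known beforehand, and 13 of 96 other strong pairs had edges as close. A broad bound domain stays open as well. The strain carries a blmp-1 transgene and blmp-1 lies on chromosome I in WBcel235, but no WS220 annotation was used here to place blmp-1 against the region.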
